A study of Mus musculus with 15 samples.

How the data were processed

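The series holds 15 bulk RNA-seq libraries of mouse bone-marrow progenitors sorted by surface markers and reporter alleles. ALP_WT (n = 3) is the all-lymphoid progenitor, sorted as Lin- Kit+ 2B4+ a4b7- Flt3high IL-7Ra+. EILP_WT (n = 3) is the early innate lymphoid progenitor, sorted as a4b7+ Tcf7+ Thy1- cells. EILP_KO (n = 2) came from the same gate in mice with 2 null Tcf7 alleles. sEILP_WT (n = 2) and cEILP_WT (n = 3) split that gate into Zbtb16low Flt3high and Zbtb16high Flt3low cells. ILCP_WT (n = 2) is the innate lymphoid cell (ILC) progenitor, sorted as Thy1+ IL-7Ra+. The labels give EILP_WT the genotype Tcf7EGFPnull/+, so EILP_WT cells carried 1 null allele. All mice were of the C57BL/6 background. Reporter strains differ between sEILP_WT and ALP_WT and between ILCP_WT and cEILP_WT. Strain and stage cannot be told apart in these comparisons or in the gene sets drawn from them. The labels do not say that replicates are separate animals, so the p-values measure the spread between samples.

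Per the labels, libraries were made with a SMARTer ultra low input kit and a Nextera XT kit. The submitters' processing notes name bcl2fastq 2.17, STAR 2.5.2b, RSEM 1.2.23 and limma without a version, with build mm10; they do not state the gene annotation. The deposited table holds log2 values: counts per 1e6 on the log2 scale, quantile-normalized across the 15 libraries, as read from the values themselves. It has 12798 genes and 24 further columns without a name or values, which were not used. No counts were analysed here, so the depth of each library is unknown and no detection limit can be given. Each library has its own lowest value, between -4.83 and -4.41, shared by 747 to 2575 genes. A gene there is called listed at the lowest value, and no fold is given where a whole group lies there.

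Groups and batches were taken from the labels: 9 libraries form batch 1 and 6 form batch 2, and sEILP_WT lies in batch 1 only. Genes with a log2 value of at least 0 in at least 2 libraries were tested, which left 12572. A single limma model (version 3.58.1 in R 4.3.3) with the group and the batch as terms was fitted to all libraries, with an intensity trend in the variance. Log2 fold changes are the model's estimates with their standard error (SE), and group values are means ± SD. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene counts as changed at an adjusted p under 0.05. The batch term itself passed for 0 genes by limma, with 954 genes at an unadjusted p under 0.05. Because this limma fit takes the deposited values as they are, the pseudocount alternative planned for other units did not apply.

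Comparisons, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule named Tcf7 first. It then named, per comparison, changed genes of at least 1 log2 unit, above the median expression of tested genes in the higher group, with no overlap between the groups' libraries and without predicted genes or immunoglobulin and T cell receptor genes: the 8 largest rises and falls for main comparisons and 4 for the others. Genes outside the rule are list members, or were chosen after their values were seen where that is said. 18 lists were tested in 7 comparisons by camera with a preset correlation of 0.01, adjusted over all 126 tests, with fry beside it: ILC regulators, ILC surface and effector genes, T lineage, Notch targets, B lineage, dendritic cell, myeloid, stem and multipotent progenitor, natural killer (NK), erythroid and megakaryocyte, mast cell and basophil, neutrophil, E and Id proteins, cell cycle, early response, interferon response, ribosomal protein and mitochondrially encoded genes. Of 51 calls, 0 held by camera with an estimated correlation. Where a list's median printed here moved by over 1.5 times or turned sign without genes whose values in a whole group lay at the lowest value, the median without them is given too. The genes of the sort gate and the reporters were read as checks. Zbtb16 is among them and on the ILC regulator list, so the lists were also tested without the gate genes. Sets of up to 200 genes that rose or fell between wild-type stages were tested in EILP_KO vs EILP_WT, again by camera.

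Tested on simulated data with known changes, the fit of EILP_KO vs EILP_WT recovered 19.4% of changes of 1 log2 unit, 64.2% of 2 and 92.4% of 4, with 6 false among 123 calls. The changed genes were drawn from those with a mean above the median. In the real fit the median SE was 0.363 for such genes and 0.677 for all tested genes, so recovery over all genes is not given by these shares. For cEILP_WT vs sEILP_WT the shares were 13.4%, 62.7% and 92.4%, with 8 false among 120 calls. Camera called the moved simulated set in 50 of 50 draws and the unmoved set in 0 of 50. The simulation shuffled residuals gene by gene, which removed any correlation between genes. It therefore does not show how often camera calls unmoved sets of correlated genes. Shuffling across all libraries also gave every group the same spread, and no group was set to the lowest value. In the real fit of EILP_KO vs EILP_WT, 5 higher and 4 lower changed genes had a whole group there. The simulated share of false calls may not hold for such genes.

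The alternatives fixed beforehand were a fit without the batch, a replicate block, each batch alone, repeated quantile normalization, no filter or a stricter filter at 3 log2 units, no variance trend, robust moderation, only the 2 groups compared and leaving out each library. Array weights, cyclic loess, lowest values as missing (8804 genes), a sex term, a shared fit lacking EILP_WT replicate 3, the lists without gate genes and further forms of the stage sets were added after the data were seen. Positions are from GENCODE vM21 (GRCm38, the same assembly as mm10), 1-based. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.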

Results

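The libraries follow lymphoid progenitors from ALP to EILP and on to ILCP, with Tcf7-null EILP beside them. Tcf7 encodes the transcription factor TCF-1. On the log2 scale of the deposited values, Tcf7 was 2.54, 2.64 and 1.91 in the ALP_WT libraries, 9.98 and 10.23 in sEILP_WT, 11.34, 11.06 and 11.14 in cEILP_WT, and 9.89, 10.81 and 11.14 in EILP_WT. It was 9.89 and 10.17 in ILCP_WT. The EILP_KO libraries held Tcf7 at 6.97 and 7.65, below every EILP_WT library and above every ALP_WT library. Tcf7 lies on chromosome 11 at 52252371 to 52283014. EILP_WT replicate 3 stood apart from the other EILP_WT libraries: 2575 genes were at its lowest value, against 1877 and 1470.

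**Figure D1:**
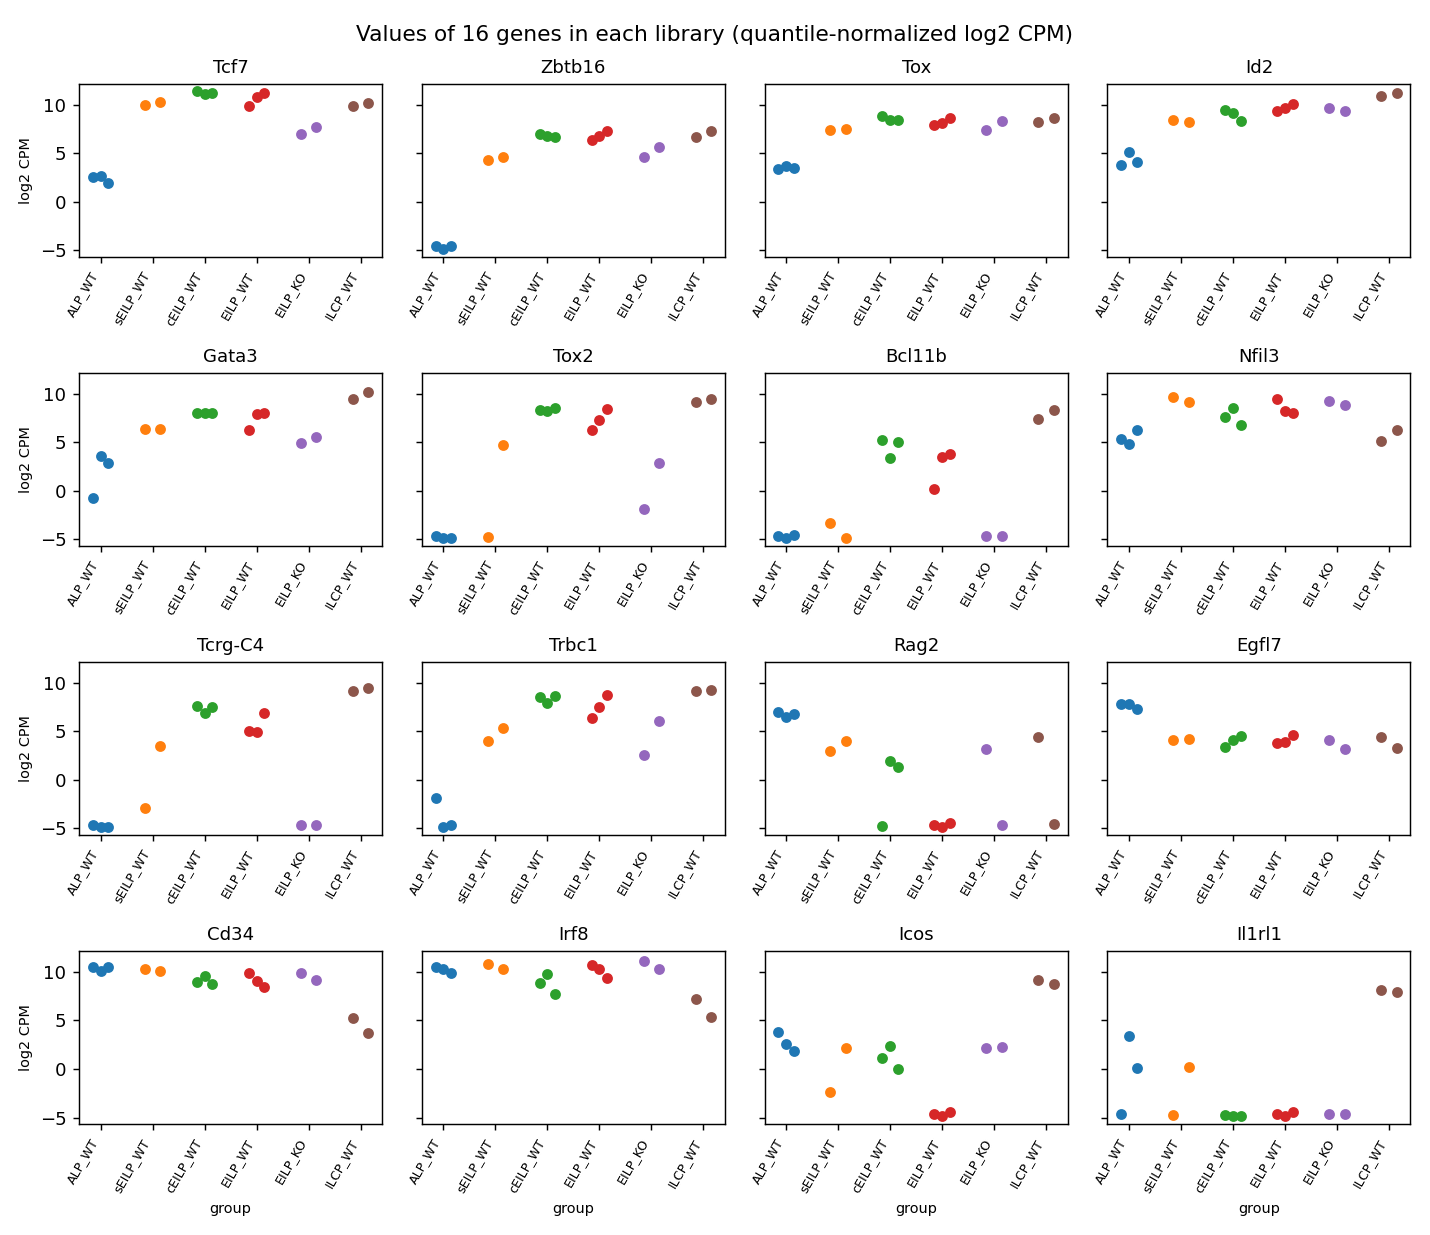
Each panel plots a gene's deposited log2 value (vertical axis) in each of the 15 libraries (points) by group (horizontal axis). Tcf7 was 6.97 and 7.65 in EILP_KO and at least 9.89 in every EILP_WT, cEILP_WT and ILCP_WT library.

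Few genes passed the threshold between EILP_KO and EILP_WT. The fit recovered 19.4% of simulated changes of 1 log2 unit, so a low count does not show that few genes differed. In EILP_KO (n = 2) against EILP_WT (n = 3), 13 genes changed, 6 higher and 7 lower, all by at least 1 log2 unit. Tcf7 fell by 3.34 (SE 0.32, limma adjusted p = 0.00151), which is 10.2-fold. Aff4, which encodes a scaffold of a transcription elongation complex, fell by 3.06 (SE 0.42, adjusted p = 0.0214), from 6.87 ± 0.40 to 3.86 ± 1.09. Tcrg-C4, a constant gene of the T cell receptor gamma locus, was 5.62 ± 1.11 in EILP_WT and listed at the lowest value in both EILP_KO libraries (adjusted p = 0.0358). Poglut1, which encodes a glucosyltransferase that modifies Notch, rose by 2.06 (SE 0.33, adjusted p = 0.0492), from 4.89 ± 0.45 to 6.92 ± 0.52. Plod1, Angptl2 and Armcx5 were lower and at the lowest value in both EILP_KO libraries, with EILP_WT means of 4.67, 4.50 and 2.51. Lrrc28 was lower at -1.55 ± 0.39 against 4.59 ± 0.82. Tnik, Epb4.1l3, Nxf2, Slc1a4 and Vill were higher, from the lowest value in every EILP_WT library to means of 4.47, 4.03, 3.79, 3.42 and 2.78. These 9 genes and Tcrg-C4 fell outside the naming rule and were chosen after their values were seen, since they complete the list of changed genes.

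The gate genes served as checks. Zbtb16 was 5.09 ± 0.75 in EILP_KO and 6.76 ± 0.47 in EILP_WT (adjusted p = 0.451), and Kit, Itga4, Itgb7 and Cd244 did not pass either. Zbtb16 passed beside Tcf7 when adjusted over the list alone (adjusted p = 0.0459). Itgb7 was 9.93 ± 0.43 against 10.08 ± 0.34. Il7r was -1.14 ± 0.22 in EILP_KO, and 3.11 ± 6.70 in EILP_WT (adjusted p = 0.625).

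T lineage genes, ILC regulators and NK genes had negative medians in EILP_KO. Of 18 measured T lineage genes, 0 rose and 0 fell over all genes by limma, where 1094 genes had an unadjusted p under 0.05, and 3 fell when adjusted over the list alone. Their median was -2.34, and camera placed the list lower (adjusted p = 6.75e-05, or adjusted p = 0.0805 with an estimated correlation). Trat1 and Bcl11b were listed at the lowest value in both EILP_KO libraries, against 4.42 ± 0.94 and 2.47 ± 1.97 in EILP_WT. Of 16 ILC regulators, 0 passed over all genes and 5 fell when adjusted over the list alone, with a median of -1.22, or -0.58 without 2 genes with a group at the lowest value (camera lower, adjusted p = 0.00286, or adjusted p = 0.428 with an estimated correlation). Without the gate gene Zbtb16, 4 of 15 fell when adjusted over the list alone (camera lower, adjusted p = 0.0104, or adjusted p = 0.461 with an estimated correlation). Their median was -0.77, or -0.40 without genes with a group at the lowest value. Tox2 was 0.52 ± 3.32 in EILP_KO and 7.30 ± 1.07 in EILP_WT, Rora 0.42 ± 7.09 and 7.04 ± 1.03, and Gata3 5.19 ± 0.42 and 7.41 ± 0.96. The 12 NK genes, with Gzma and Eomes among them, had a median of -3.36, or -0.62 without 6 genes with a group at the lowest value, and 0 calls, also when adjusted over the list alone (camera lower, adjusted p = 0.012, or adjusted p = 0.502 with an estimated correlation).

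Myeloid and cell cycle genes had positive medians. Erythroid and megakaryocyte genes and mast cell and basophil genes had larger positive medians than myeloid genes. Neutrophil genes and Notch targets had negative medians. For these lists, several of them short, only the sign of the median is described and no shift is claimed. All 18 myeloid genes missed the threshold, also when adjusted over the list alone, while 15 of 18 were positive, with a median of 0.78 (camera higher, adjusted p = 0.00437, or adjusted p = 0.428 with an estimated correlation). The neutrophil elastase gene Elane was 8.55 ± 1.56 in EILP_KO and 4.45 ± 1.42 in EILP_WT, Lyz2 6.73 ± 0.54 and 4.93 ± 1.13, and the myeloperoxidase gene Mpo 11.78 ± 0.13 and 9.87 ± 1.69. All 20 cell cycle genes were positive, with a median of 0.46 and 0 calls, also when adjusted over the list alone (camera higher, adjusted p = 1.02e-05, or adjusted p = 0.307 with an estimated correlation). Ccnb2 was 7.44 ± 0.13 against 6.57 ± 0.35. The 76 ribosomal protein genes had a median of 0.11 and 0 calls, also when adjusted over the list alone (camera higher, adjusted p = 0.0238, or adjusted p = 0.814 with an estimated correlation). In the mean, B lineage genes were positive at 0.64 and in the median negative at -0.12 (-0.23 without 8 genes with a group at the lowest value), and stem and multipotent progenitor genes likewise had a mean of 0.53 and a median of -0.17 (camera adjusted p = 0.73 and 0.977).

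The Tcf7 comparison rests on few libraries. Without EILP_WT replicate 3, 2 genes passed, without EILP_WT replicate 1, 5, without EILP_WT replicate 2, 8, and without EILP_KO replicate 1 or replicate 2, 43 and 53. Of these, 0, 1, 4, 4 and 1 were higher in that order, and 2, 3, 4, 5 and 7 were among the 13. Batch 1 alone gave 39 genes, 2 of them among the 13, and batch 2 alone, with 1 library per group, 0. Tcf7 fell by 3.38 in batch 1 (adjusted p = 0.0391) and by 3.49 in batch 2 (0.185), and its adjusted p was 0.105 with a sex term and 0.162 in a fit of the 2 groups alone.

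The set of genes that rose from ALP_WT to sEILP_WT shifted down in EILP_KO against EILP_WT. Of its 62 genes, 1 passed by limma, Tcf7 itself, and 10 were positive in EILP_KO vs EILP_WT (16.1%, against 52.8% of all genes), with a median of -0.49 (camera lower, adjusted p = 3.75e-12, or adjusted p = 0.0426 with an estimated correlation). Without the sort gate genes, Tcf7 among them, 58 genes had a median of -0.48 (adjusted p = 3.06e-10). The 39 genes that fell from ALP_WT to sEILP_WT had a median of 0.03, with camera's direction lower (adjusted p = 0.794), so median and test differed in sign. The sets of 200 genes higher and 200 lower in ILCP_WT than in cEILP_WT had medians of -0.10 and 0.14 (adjusted p = 0.367 and 0.625). Because cEILP_WT vs sEILP_WT gave no changed gene, the 100 genes at each end of its test were added after the data were seen. Those toward cEILP_WT, of which Tcf7, Tcrg-C4 and Angptl2 passed, had a median of -0.55 in EILP_KO vs EILP_WT (adjusted p = 2.46e-11, or adjusted p = 0.00549 with an estimated correlation). Those toward sEILP_WT had a median of 0.21 (adjusted p = 0.0129, or adjusted p = 0.165 with an estimated correlation), and of 0.09 without EILP_KO replicate 1 (p = 0.635, camera).

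**Figure D2:**
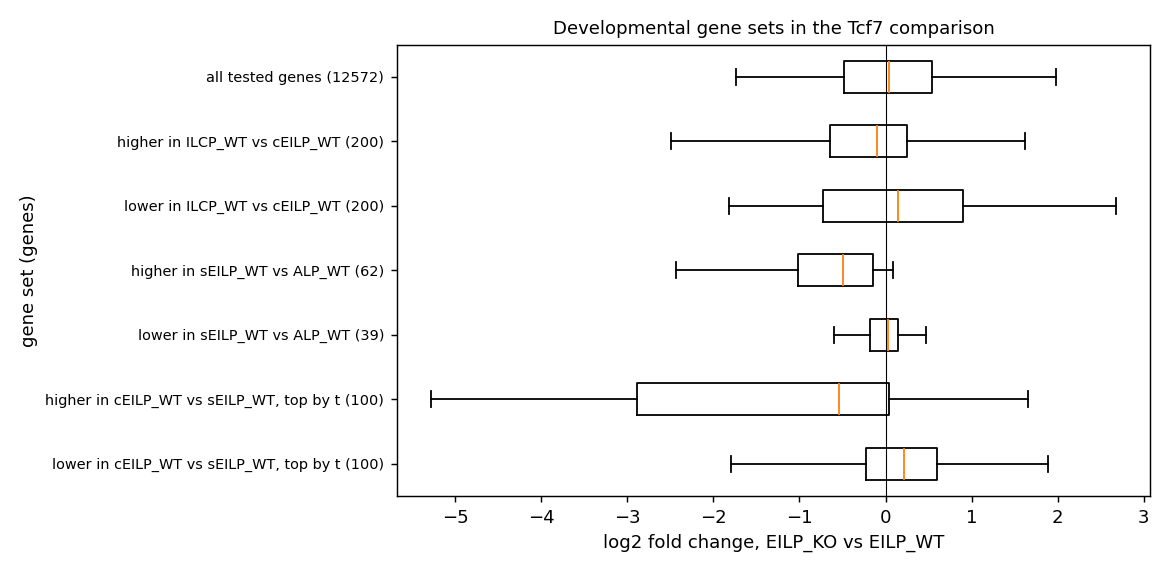
Boxes show the log2 fold change in EILP_KO vs EILP_WT (horizontal axis) of all tested genes and of sets of genes that differed between wild-type stages (vertical axis, genes in parentheses), with the median, the quartiles and whiskers from the 10% to the 90% point. The set higher in sEILP_WT than in ALP_WT had a median of -0.49.

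From ALP_WT to EILP_WT (n = 3 each), 404 genes changed, 215 higher and 189 lower, and 349 of them moved by at least 1 log2 unit. A fit of these 2 groups alone, in place of all libraries, gave 81 changed genes. Without EILP_WT replicate 3, 97 were higher and 74 lower, and without ALP_WT replicates 1, 2 and 3 the counts were 143 and 97, 151 and 71, and 180 and 94. The largest rises by the rule included Tox2, Fgf3, Megf10, Rxrg and Fgf15, all at the lowest value in every ALP_WT library. In EILP_WT they reached 7.30 ± 1.07, 6.62 ± 0.96, 5.75 ± 0.53, 5.54 ± 1.56 and 5.25 ± 1.90 (limma adjusted p = 0.00369, 0.00109, 0.0118, 0.00233 and 0.0111). Tox2 encodes an HMG-box transcription factor. Fgf3 and Fgf15 encode fibroblast growth factors and lie on chromosome 7, at 144838083 to 144844436 and 144896531 to 144900953. Serpine2 and Spon2 were 7.43 ± 1.06 and 5.68 ± 1.33 in EILP_WT and at the lowest value in 2 of 3 ALP_WT libraries. The largest falls were Rag2, Paqr5, Siglech, Emp1, Nav1, Hnf4a and Nlrp1a, all at the lowest value in every EILP_WT library. In ALP_WT they were 6.76 ± 0.25, 6.53 ± 0.50, 6.38 ± 1.12, 5.99 ± 0.68, 5.47 ± 0.75, 5.15 ± 1.49 and 4.96 ± 0.17. Cmah was 7.42 ± 0.78 in ALP_WT and -1.97 ± 4.39 in EILP_WT. As checks of the gate, Tcf7 rose by 8.34, Itgb7 and Itga4 rose by 3.09 and 2.05, and Flt3 fell by 3.39. Zbtb16 rose from at or near the lowest value, at -4.65 ± 0.16, to 6.76 ± 0.47. Thy1 rose when adjusted over the list alone (6.13, SE 1.67, adjusted p = 0.0754 over all genes and 0.00485 over the list).

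Among the 18 lists, ILC regulators had the most rises. Of 16 measured, 9 rose, 0 fell and 7 did not pass, and 12 rose when adjusted over the list alone. Without the gate gene Zbtb16 the counts were 8 and 11. The median was 5.66 (camera higher, adjusted p = 1.37e-16, or adjusted p = 0.0805 with an estimated correlation). Tox rose by 4.84 (SE 0.24, adjusted p = 5.3e-07) and Id2, which encodes an inhibitor of E proteins, by 5.39 (SE 0.36, adjusted p = 9.57e-06). Gata3 rose by 5.92 (SE 0.70) and Nfil3 by 2.98 (SE 0.53), Runx3 by 2.15, and Bcl11b and Lef1 from near the lowest value to 2.47 ± 1.97 and 3.15 ± 3.60. Of 18 T lineage genes, 4 rose, with Txk, Bcl11b and Trat1 among them, and 5 rose when adjusted over the list alone (15 of 18 positive, median 1.5, or 0.72 without 6 genes with a group at the lowest value, camera higher, adjusted p = 0.00241, or adjusted p = 0.0888 with an estimated correlation). Of 12 NK genes, Ccl5 and Nkg7 rose, and 4 when adjusted over the list alone (median 3.52, or 1.43 without 5 genes with a group at the lowest value, camera higher, adjusted p = 0.00259, or adjusted p = 0.428 with an estimated correlation). Of 14 ILC surface and effector genes, Il12rb2, Cxcr5 and Il2rb rose and Icos fell, with 4 rises and 1 fall when adjusted over the list alone (median 0.79, or 2.38 without 5 genes with a group at the lowest value, camera adjusted p = 0.111). Chosen after their values were seen, Cpa3, a mast cell protease gene, rose by 6.81 (SE 0.39) to 9.29 ± 0.24, and the survival gene Bcl2 rose by 2.16 (SE 0.17).

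Transcripts of part of the T cell receptor gene segments rose. This group was defined by symbol after its values were seen, and neighbouring segments can share reads. Of 29 measured segments, 14 rose in EILP_WT against ALP_WT, 0 fell and 15 did not pass, and all 29 were positive, with a median of 5.70. Trbc1 rose from -3.78 ± 1.69 to 7.51 ± 1.19 and Tcrg-C1 from -0.19 ± 4.14 to 7.15 ± 1.10, while Trbj1-1 was at the lowest value in every ALP_WT library and 4.96 ± 1.37 in EILP_WT. In EILP_KO against EILP_WT, 0 of the 29 were positive, the median was -3.42, and Tcrg-C4 was the segment that passed. Tcrg-C2 was listed at the lowest value in both EILP_KO libraries and was 2.92 ± 1.54 in EILP_WT (adjusted p = 0.0995). Repeated quantile normalization and cyclic loess kept 29 and 0 as the positive counts, but the former lost the call of Tcrg-C4. Without EILP_WT replicate 3, 4 segments rose against ALP_WT in place of 14, and without ALP_WT replicates 1, 2 and 3 the counts were 10, 6 and 5. Without EILP_WT replicate 2, 7 rose. In EILP_KO vs EILP_WT, Tcrg-C4 did not pass when any of the 5 libraries was left out. The median of the segments there was -2.14 without EILP_KO replicate 1, with 3 positive.

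Part of the B lineage, stem cell and cell cycle genes fell. Of 15 B lineage genes, Rag1, Ighm, Rag2 and Mzb1 fell, and 8 fell when adjusted over the list alone (median -4.39, or -2.70 without 7 genes with a group at the lowest value, camera lower, adjusted p = 2.92e-05, or adjusted p = 0.092 with an estimated correlation). Rag1 was 3.04 ± 1.15 in ALP_WT and at the lowest value in every EILP_WT library, and Ighm fell by 1.37 (SE 0.20). Of 18 stem and multipotent progenitor genes, Egfl7, Cd34, Mef2c and Hoxa10 fell and Mycn rose, with 8 falls and 1 rise when adjusted over the list alone (median -1.20, camera lower, adjusted p = 5.87e-05, or adjusted p = 0.0868 with an estimated correlation). Egfl7 fell by 3.54 (SE 0.51) and Cd34 from 10.36 ± 0.22 to 9.11 ± 0.70, while Mycn rose by 2.71 (SE 0.28). All 20 cell cycle genes were negative, and Ccnb2, Mcm6, Top2a and Cdk1 fell, with 11 falls when adjusted over the list alone (median -0.76, camera lower, adjusted p = 3.27e-09, or adjusted p = 0.165 with an estimated correlation). Of 12 interferon response genes, Oasl2 fell, and 1 fell when adjusted over the list alone (median -1.36, camera lower, adjusted p = 0.0159, or adjusted p = 0.314 with an estimated correlation). The 76 ribosomal protein genes had 0 calls, also when adjusted over the list alone, and a median of -0.30 (camera lower, adjusted p = 6.37e-08, or adjusted p = 0.592 with an estimated correlation).

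Other lists had at most 5 calls each. Of 20 dendritic cell genes, Batf3 rose and Ccr9, Runx2, Tcf4 and Siglech fell, with 4 rises and 6 falls when adjusted over the list alone (median -0.27, or -0.09 without 5 genes with a group at the lowest value, camera adjusted p = 0.316). Of 18 myeloid genes, Ccr2 and Calr rose and Lyz2 fell, with 2 rises and 2 falls when adjusted over the list alone. Their median of -0.37 and camera's upward direction differed in sign (adjusted p = 0.949). Of 3 Notch targets, Hes1 rose and Myc and Notch1 fell, as they did when adjusted over the list alone, with a median of -1.19 and a mean of 0.52 (camera adjusted p = 0.286). Of 4 E and Id genes, Id2 rose and Tcf4 fell, also when adjusted over the list alone (camera adjusted p = 0.397). Itga2b rose among 13 erythroid and megakaryocyte genes and Cpa3 among 8 mast cell and basophil genes, 1 rise in each list when adjusted over the list alone (camera adjusted p = 0.0549 and 0.38). The mast cell and basophil median of -0.25 and camera's upward direction differed in sign, and the median was 0.03 without 1 gene with a group at the lowest value. The 9 neutrophil, 9 early response and 11 mitochondrially encoded genes had 0 calls, also when adjusted over the list alone (medians -3.00, -0.66 and 0.06; camera adjusted p = 0.129, 0.227 and 0.958). In all, 171 genes passed without EILP_WT replicate 3, 222 without ALP_WT replicate 2 and 240 without ALP_WT replicate 1. Batch 1 alone leaves 1 ALP_WT library and batch 2 alone 1 EILP_WT library, so a count from either batch says little here.

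**Figure D3:**
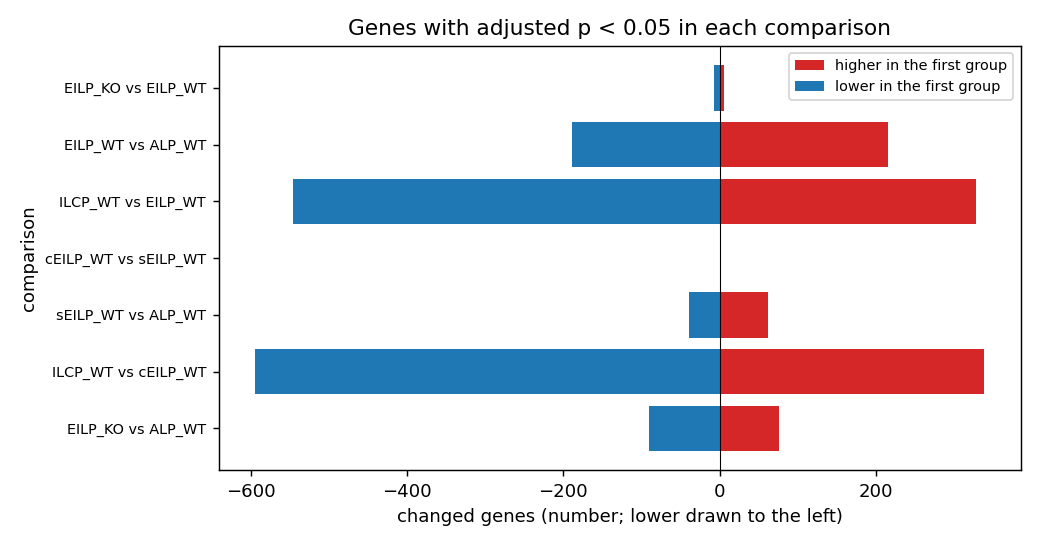
Bars give the number of genes at a limma adjusted p under 0.05 (horizontal axis) that were higher (right) or lower (left) in the first-named group of each comparison (vertical axis). ILCP_WT vs cEILP_WT had 338 higher and 594 lower genes.

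From EILP_WT to ILCP_WT (n = 3 and n = 2), 874 genes changed, 328 higher and 546 lower, and 736 of them moved by at least 1 log2 unit. A fit of these 2 groups alone, in place of all libraries, gave 3 changed genes. Without ILCP_WT replicate 1, 140 were higher and 597 lower, and without ILCP_WT replicate 2, 157 and 592. Of these, 420 and 453 genes were among the 874. Among the 595 changed genes that were above the lowest value in every library of both groups, 65.7% were lower. With cyclic loess, 447 of 838 changed genes were lower. The largest rises by the rule were Icos, Ccr9, Il1rl1, Pxdc1, Camk4, Tnfrsf25, Ccr6 and Fam20a, all at the lowest value in every EILP_WT library. Il1rl1 was 8.07 and 7.93 in the ILCP_WT libraries, and the others in that order were 8.94 ± 0.27, 8.52 ± 0.35, 7.68 ± 0.36, 6.94 ± 0.27, 6.30 ± 0.93, 6.08 ± 1.83 and 5.75 ± 1.12. Icos encodes a costimulatory receptor and Il1rl1 the receptor for interleukin 33. The largest falls were Cercam, Itga2b, Sh2d5, Rnd3, Drc7, Sirpa and Gpr146, at the lowest value in both ILCP_WT libraries, with EILP_WT means of 6.30, 5.97, 5.82, 5.76, 5.70, 5.70 and 5.57. Rab44 was 8.08 ± 0.11 in EILP_WT and -2.35 ± 3.12 in ILCP_WT. Of the gate genes, Flt3 fell by 5.61, Itga4 by 1.43 and Cd244 by 2.11. Il7r was 10.71 ± 0.18 in ILCP_WT and 3.11 ± 6.70 in EILP_WT (adjusted p = 0.0968, or 0.0247 when adjusted over the list alone), and Thy1 was 4.92 ± 0.09 in ILCP_WT and 1.59 ± 0.89 in EILP_WT (adjusted p = 0.311, or 0.135 when adjusted over the list alone).

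Part of the surface receptor and effector genes of ILCs rose. Of 14 measured genes, Icos, Il17rb, Ltb, Lta, Il1rl1, Il18r1 and Tnfsf11 rose, 0 fell and 7 did not pass, and 9 rose when adjusted over the list alone (median 4.50, or 2.97 without 4 genes with a group at the lowest value, camera higher, adjusted p = 3.35e-08, or adjusted p = 0.0805 with an estimated correlation). Ltb, which encodes lymphotoxin beta, rose by 4.87 (SE 0.61) to 9.46 ± 0.08, and Il17rb by 4.13 (SE 0.49) to 8.52 ± 0.03. The 30 interleukin receptor and 16 chemokine receptor genes were grouped by symbol after their values were seen. Of the interleukin receptors, 8 rose, among them Il2rg by 2.44 (SE 0.25), and Il23r, listed at the lowest value in every EILP_WT library and 4.91 and 5.09 in ILCP_WT. Another 5 fell, with Il1rap and Il21r at the lowest value in both ILCP_WT libraries against 4.97 ± 0.65 and 3.68 ± 1.67 in EILP_WT. Of the chemokine receptors, Ccr9, Xcr1, Ccr7, Ccr10 and Ccr6 rose and Cx3cr1 fell. Cxcr6 was 10.10 ± 0.33 in ILCP_WT and at the lowest value in 2 of 3 EILP_WT libraries (adjusted p = 0.0553). Without ILCP_WT replicate 1, 3 interleukin and 2 chemokine receptors rose, and without ILCP_WT replicate 2, 4 and 2. Chosen after their values were seen, Lmo4 rose by 3.94 (SE 0.40), Tgfbr2 by 3.59 (SE 0.39) and Cd82 by 3.61 (SE 0.42).

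Part of the progenitor and myeloid genes fell, as did 2 ILC regulators. Of 16 ILC regulators, Runx3 fell by 1.24 (SE 0.22) and Nfil3 by 2.79 (SE 0.58) and 0 rose, whereas 5 rose and 2 fell when adjusted over the list alone (median 2.60, camera higher, adjusted p = 0.0185, or adjusted p = 0.502 with an estimated correlation). Of 18 T lineage genes, Cd2 rose, with 4 rises and 1 fall when adjusted over the list alone (median 2.84, camera higher, adjusted p = 0.00564, or adjusted p = 0.103 with an estimated correlation). Of 18 stem and multipotent progenitor genes, 8 fell, and 9 when adjusted over the list alone (median -1.35, camera lower, adjusted p = 7.49e-05, or adjusted p = 0.0871 with an estimated correlation). Among them Cd34 fell by 4.53 (SE 0.31), Sox4 by 1.51 (SE 0.18), Mef2c by 2.62 (SE 0.43) and Bcl11a by 2.70 (SE 0.48). Of 18 myeloid genes, Csf3r, Spi1, Prtn3, Calr and Cebpa fell, with 8 falls and 1 rise when adjusted over the list alone (median -1.62, camera lower, adjusted p = 0.00286, or adjusted p = 0.398 with an estimated correlation). Csf3r was listed at the lowest value in both ILCP_WT libraries against 5.47 ± 1.16 in EILP_WT, and Spi1, which encodes PU.1, fell by 5.13 (SE 0.77). Chosen after their values were seen, Plac8 fell by 4.25 (SE 0.22), Ncf1 by 4.26 (SE 0.31), Cd24a by 3.91 (SE 0.29) and Myb from 8.39 ± 0.43 to 6.20 ± 0.00. Of 76 ribosomal protein genes, 8 fell, including Rpl4, Rps25 and Rpl3, and 37 fell when adjusted over the list alone (median -0.51, camera lower, adjusted p = 4.05e-15, or adjusted p = 0.436 with an estimated correlation).

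Of 20 dendritic cell genes, Ccr9 and Xcr1 rose and Irf8 fell by 3.65 (SE 0.35), with 2 rises and 2 falls when adjusted over the list alone (camera adjusted p = 0.651). Cell cycle genes had 0 calls, also when adjusted over the list alone. Their median of -0.16 differed in sign from their mean of 0.04 and from camera (adjusted p = 0.949), and cyclic loess turned the median to 0.01. The 12 NK genes had a median of 1.35 (camera adjusted p = 0.196), with 0 calls, also when adjusted over the list alone. Batch 2 alone gave 0 genes, and ILCP_WT has 1 library in each batch.

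From sEILP_WT to cEILP_WT (n = 2 and n = 3), 0 genes passed by limma, with 647 at an unadjusted p under 0.05 and a smallest adjusted p of 0.102. Limma without the variance trend gave 9 genes, and 7 passed without sEILP_WT replicate 2. The gate genes differed in value as sorted: Zbtb16 was 6.83 ± 0.12 in cEILP_WT and 4.44 ± 0.23 in sEILP_WT (adjusted p = 0.663, or 0.0196 when adjusted over the list alone), and Flt3 was 7.31 ± 0.84 and 9.12 ± 0.49. Tcf7 and Kit were also higher in cEILP_WT when adjusted over the list alone (adjusted p = 0.0346 for each). Bcl11b was 4.53 ± 1.05 in cEILP_WT and -4.06 ± 1.08 in sEILP_WT (adjusted p = 0.393). Txk was 4.87 ± 0.75 against -4.77 ± 0.07, at the lowest value in both sEILP_WT libraries, and Tox2 was 8.36 ± 0.18 against 0.01 ± 6.70. Of the 16 ILC regulators, 5 rose and 1 fell when adjusted over the list alone (median 0.79, camera higher, adjusted p = 6.9e-05, or adjusted p = 0.307 with an estimated correlation). Zbtb16, on which these groups were sorted, is on that list. Without it 3 rose and 0 fell when adjusted over the list alone (median 0.62, camera higher, adjusted p = 0.000733, or adjusted p = 0.344 with an estimated correlation). Of 18 T lineage genes, 2 rose when adjusted over the list alone (median 0.85, or 0.53 without 4 genes with a group at the lowest value, camera higher, adjusted p = 0.0135, or adjusted p = 0.148 with an estimated correlation).

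Dendritic cell genes had a negative median in cEILP_WT against sEILP_WT. Of 20 measured, 0 passed over all genes and Irf8 and Cd74 were lower in cEILP_WT when adjusted over the list alone (median -1.04, camera lower, adjusted p = 0.00437, or adjusted p = 0.28 with an estimated correlation). Irf8 was 8.77 ± 1.00 in cEILP_WT and 10.56 ± 0.39 in sEILP_WT, Cd74 5.15 ± 1.78 and 8.44 ± 0.43, and the class II gene H2-Ab1 5.81 ± 0.21 and 7.16 ± 0.11. Cell cycle genes had a median of -0.34 and interferon response genes of -0.71, both with 0 calls, also when adjusted over the list alone. Camera placed both lower (adjusted p = 7.5e-05 and 0.0223, or adjusted p = 0.342 for each with an estimated correlation). sEILP_WT lies in batch 1 only, where the comparison holds 2 libraries per group and gave 0 genes.

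**Figure D4:**
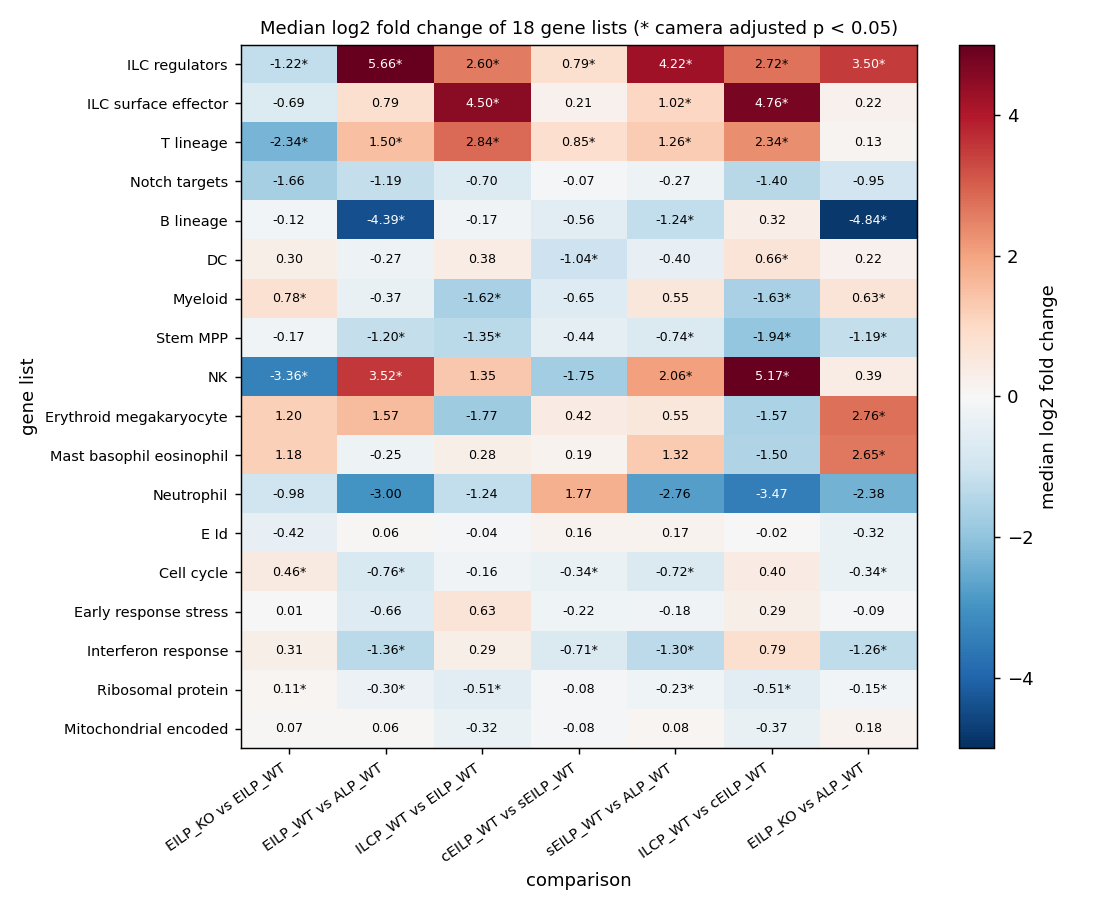
Each cell gives the median log2 fold change of a gene list (vertical axis) in a comparison (horizontal axis), with an asterisk where camera's adjusted p is under 0.05 at the preset correlation. Of these 51 calls, 0 held with an estimated correlation. ILC regulators ranged from -1.22 in EILP_KO vs EILP_WT to 5.66 in EILP_WT vs ALP_WT.

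In sEILP_WT against ALP_WT (n = 2 and n = 3), 101 genes changed, 62 higher and 39 lower. Fgf3 and Perp were at the lowest value in every ALP_WT library and reached 5.24 ± 0.17 and 5.08 ± 0.36 (limma adjusted p = 0.0126 for each), and Itga2b rose to 5.90 ± 0.65 and Cxcr5 to 4.32 and 5.68. Egfl7 fell by 3.55 (SE 0.60), Tspan13 by 2.53 (SE 0.32), Cnn3 by 2.53 (SE 0.40) and Tgtp2 by 2.21 (SE 0.42). Of 16 ILC regulators, 6 rose (Zbtb16, Tox, Id2, Runx3, Gata3 and Nfil3) and 7 when adjusted over the list alone, against 5 and 6 without the gate gene Zbtb16 (median 4.22, camera higher, adjusted p = 1.84e-13, or adjusted p = 0.0868 with an estimated correlation). Tox rose by 4.21 (SE 0.28), Nfil3 by 3.71 (SE 0.63) and Gata3 by 5.29 (SE 0.83). Bcl11b, at -4.06 ± 1.08, and the T lineage list as a whole had 0 calls, also when adjusted over the list alone (median 1.26, camera higher, adjusted p = 0.0233, or adjusted p = 0.185 with an estimated correlation). Of 15 B lineage genes, Rag1 and Ighm fell, and 6 when adjusted over the list alone (median -1.24, or -0.52 without 4 genes with a group at the lowest value, camera lower, adjusted p = 0.00073, or adjusted p = 0.165 with an estimated correlation). The 20 cell cycle genes had a median of -0.72, with 0 calls and 2 falls when adjusted over the list alone (camera lower, adjusted p = 4.24e-08, or adjusted p = 0.192 with an estimated correlation). Of 14 ILC surface and effector genes, Il12rb2 and Cxcr5 rose, and of 12 NK genes Ccl5, with 3 and 1 rises when adjusted over the list alone (medians 1.02 and 2.06, the latter 1.06 without 5 genes with a group at the lowest value). Camera placed both higher (adjusted p = 0.0101 and 0.0159, or adjusted p = 0.263 and 0.502 with an estimated correlation). Of 18 stem and multipotent progenitor genes, Mycn rose and Egfl7 fell, also when adjusted over the list alone (median -0.74, camera lower, adjusted p = 0.0233, or adjusted p = 0.307 with an estimated correlation). The interferon response and ribosomal protein lists had 0 calls, also when adjusted over the list alone (medians -1.30 and -0.23, camera lower, adjusted p = 0.0245 and 5.94e-07, or adjusted p = 0.342 and 0.646 with an estimated correlation). Without ALP_WT replicate 1, sEILP_WT replicate 1 or sEILP_WT replicate 2, 27, 26 and 20 genes passed, of which 3, 8 and 8 were lower. Without ALP_WT replicate 2, 55 were higher and 21 lower.

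In ILCP_WT against cEILP_WT (n = 2 and n = 3), 932 genes changed, 338 higher and 594 lower, and of 664 above the lowest value in every library of both groups, 64.8% were lower. Without ILCP_WT replicates 1 and 2, 135 were higher and 585 lower, and 153 and 601, with 422 and 463 of these genes among the 932. Without cEILP_WT replicates 1, 2 and 3 the counts were 226 and 364, 215 and 333, and 181 and 328. With cyclic loess, 460 of 846 changed genes were lower, and with a sex term 145 genes passed, 35 higher and 110 lower. Every cEILP_WT library and no ILCP_WT library had Y reads, so sex and stage cannot be told apart in this comparison. Stab2, a scavenger receptor gene, Pxdc1 and Il1rl1 were at the lowest value in every cEILP_WT library. In ILCP_WT, Stab2 was 9.99 ± 0.16, Pxdc1 7.68 ± 0.36 and Il1rl1 8.07 and 7.93. Ccr9 rose to 8.52 ± 0.35. Itga2b, Sstr2, Drc7 and Sh2d5 were 7.27 ± 0.19, 6.89 ± 0.42, 6.21 ± 0.38 and 6.10 ± 0.16 in cEILP_WT and at the lowest value in both ILCP_WT libraries. ILC surface and effector genes rose for 7 of 14, and for 8 when adjusted over the list alone (median 4.76, camera higher, adjusted p = 6.29e-07, or adjusted p = 0.0805 with an estimated correlation), Icos from 1.15 ± 1.17 to 8.94 ± 0.27. Stem and multipotent progenitor genes fell for 8 of 18, and for 9 when adjusted over the list alone (median -1.94, camera lower, adjusted p = 1.02e-05, or adjusted p = 0.0852 with an estimated correlation), Cd34 by 4.50 (SE 0.31). Of 18 myeloid genes, Csf3r, Calr and Spi1 fell and Ccr2 rose, with 7 falls and 1 rise when adjusted over the list alone (median -1.63, camera lower, adjusted p = 0.00238, or adjusted p = 0.379 with an estimated correlation). Of 16 ILC regulators, Id2 rose and Runx3 fell, with 4 rises and 2 falls when adjusted over the list alone (median 2.72, camera higher, adjusted p = 0.0166, or adjusted p = 0.502 with an estimated correlation). Of 18 T lineage genes, Cd2 rose, and 1 when adjusted over the list alone (median 2.34, camera higher, adjusted p = 0.0349, or adjusted p = 0.222 with an estimated correlation). Of 12 NK genes, Ncr1 rose, and 2 when adjusted over the list alone (median 5.17, camera higher, adjusted p = 0.0025, or adjusted p = 0.428 with an estimated correlation). Of 20 dendritic cell genes, Ccr9, Cd74, Xcr1, H2-Ab1 and Batf3 rose and Irf8 fell, with 6 rises and 2 falls when adjusted over the list alone (median 0.66, or 2.33 without 4 genes with a group at the lowest value, camera higher, adjusted p = 0.0169, or adjusted p = 0.342 with an estimated correlation). Of 76 ribosomal protein genes, 14 fell, and 31 when adjusted over the list alone (median -0.51, camera lower, adjusted p = 1.17e-13, or adjusted p = 0.461 with an estimated correlation). Of 15 B lineage genes, Dntt, Ly6d and Vpreb3 fell, with 4 falls when adjusted over the list alone. The median of 0.32 (0.69 without 8 genes with a group at the lowest value) differed in sign from the mean of -1.04 and from camera (adjusted p = 0.61).

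In EILP_KO against ALP_WT (n = 2 and n = 3), 167 genes changed, 76 higher and 91 lower. Tcf7 rose by 4.99 (SE 0.32, limma adjusted p = 1.14e-05), from 2.36 ± 0.39 to 7.31 ± 0.48, and the gate genes Itgb7 and Itga4 rose by 2.98 and 1.56. Chad, Megf10 and Lef1 reached 6.06 ± 0.75, 5.91 ± 0.01 and 5.23 ± 0.90 from at or near the lowest value. Cmah, Rgl1, Emp1 and Ddx4 were at the lowest value in both EILP_KO libraries, against 7.42 ± 0.78, 6.73 ± 0.76, 5.99 ± 0.68 and 5.26 ± 0.13 in ALP_WT. Of 16 ILC regulators, Zbtb16, Tox, Id2, Runx3, Nfil3 and Lef1 rose, and 9 rose when adjusted over the list alone, against 5 and 8 without the gate gene Zbtb16 (median 3.50, camera higher, adjusted p = 1.34e-11, or adjusted p = 0.0888 with an estimated correlation). Tox rose by 4.44 (SE 0.26), Id2 by 5.15 (SE 0.40), Runx3 by 2.24 (SE 0.22) and Nfil3 by 3.52 (SE 0.58). The 18 T lineage genes had 0 calls, also when adjusted over the list alone, and a median of 0.13, or -0.40 without 10 genes with a group at the lowest value, with a mean of -0.15 (camera lower, adjusted p = 0.92), and repeated quantile normalization put the median at 0. Of 15 B lineage genes, Ighm and Rag1 fell, with 7 falls and 1 rise when adjusted over the list alone (median -4.84, or -1.75 without 6 genes with a group at the lowest value, camera lower, adjusted p = 6.9e-05, or adjusted p = 0.103 with an estimated correlation). Of 18 stem and multipotent progenitor genes, Egfl7 fell and Mycn rose, with 7 falls and 1 rise when adjusted over the list alone (median -1.19, camera lower, adjusted p = 5.12e-05, or adjusted p = 0.0868 with an estimated correlation). All 13 erythroid and megakaryocyte genes were positive with 0 calls and 1 rise when adjusted over the list alone (median 2.76, camera higher, adjusted p = 0.00073, or adjusted p = 0.307 with an estimated correlation), Itga2b at 4.78 ± 1.98 against -2.29 ± 4.19. Of 18 myeloid genes, Calr and Ccr2 rose, and 3 when adjusted over the list alone (median 0.63, camera higher, adjusted p = 0.0184, or adjusted p = 0.489 with an estimated correlation). Of 8 mast cell and basophil genes, Cpa3 rose, and 1 when adjusted over the list alone (median 2.65, camera higher, adjusted p = 0.0299, or adjusted p = 0.466 with an estimated correlation). Camera placed the cell cycle, interferon response and ribosomal protein lists lower (medians -0.34, -1.26 and -0.15; adjusted p = 0.0148, 0.0339 and 0.00073, or adjusted p = 0.519, 0.371 and 0.769 with an estimated correlation). They had 0 calls, with 0, 1 and 0 falls when adjusted over the list alone. Without ALP_WT replicate 1, 46 were higher and 47 lower, and without ALP_WT replicate 2, 65 and 47. Without EILP_KO replicates 1 and 2 the counts were 44 and 113, and 29 and 73, with 74 and 52 of these genes among the 167.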

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

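Array weights, cyclic loess, lowest values as missing and the sex term were chosen after the data were seen, as were the stage sets from cEILP_WT vs sEILP_WT and without sort gate genes. The pseudocount alternative was not run, since the unit is log2. Where a group was left with 1 library, that library was assumed to vary like the other groups. The counts of changed genes were 13 in EILP_KO vs EILP_WT, 404 in EILP_WT vs ALP_WT, 874 in ILCP_WT vs EILP_WT, 0 in cEILP_WT vs sEILP_WT, 101 in sEILP_WT vs ALP_WT, 932 in ILCP_WT vs cEILP_WT and 167 in EILP_KO vs ALP_WT. With a replicate block they were 0, 160, 345, 0, 16, 338 and 84; the numbers do not pair the samples, since deviations of libraries sharing a number correlated at r = -0.054 to 0.049, so the block costs degrees of freedom. In the 6 comparisons with lost genes, their log2 fold changes were in the median 0.98 to 1.01 times those without the block, with standard errors 1.09 to 1.24 times as large. In batch 2 every group present but ALP_WT had 1 library. The spread there rested on the 2 ALP_WT libraries, so a lack of calls in batch 2 says little. Batch 2 alone gave 0 in EILP_KO vs EILP_WT, EILP_WT vs ALP_WT, ILCP_WT vs EILP_WT, ILCP_WT vs cEILP_WT and EILP_KO vs ALP_WT, with 6 libraries in the fit. Batch 1 alone gave 39, 216 and 163 in EILP_KO vs EILP_WT, EILP_WT vs ALP_WT and sEILP_WT vs ALP_WT. A fit of only the 2 groups compared gave 0, 81, 3, 43, 102 and 18 in the comparisons other than cEILP_WT vs sEILP_WT. Such a fit has fewer samples and takes its spread from those groups alone. SDs of deviations from the group mean were 1.54 to 1.83 in EILP_WT libraries. They were 1.17 to 1.40 in ALP_WT and cEILP_WT, which also have n = 3. The shared fit may thus understate the spread of EILP_WT, and how much this adds to the counts was not tested. For the further alternatives the cause was not tested. Limma without the trend gave 246, 561, 9, 60 and 566 in EILP_WT vs ALP_WT, ILCP_WT vs EILP_WT, cEILP_WT vs sEILP_WT, sEILP_WT vs ALP_WT and ILCP_WT vs cEILP_WT. Array weights gave 2, 224, 354, 1 and 515 in EILP_KO vs EILP_WT, EILP_WT vs ALP_WT, ILCP_WT vs EILP_WT, cEILP_WT vs sEILP_WT and ILCP_WT vs cEILP_WT. The sex term gave 0, 14, 145 and 94 in EILP_KO vs EILP_WT, sEILP_WT vs ALP_WT, ILCP_WT vs cEILP_WT and EILP_KO vs ALP_WT. In EILP_KO vs EILP_WT, repeated quantile normalization gave 8, the stricter filter 7 and lowest values as missing 4. No batch term gave 1 in cEILP_WT vs sEILP_WT. Leaving out 1 library gave 2 (without EILP_WT replicate 3) to 53 (without EILP_KO replicate 2) in EILP_KO vs EILP_WT, with 5, 8 and 43 without EILP_WT replicates 1 and 2 and EILP_KO replicate 1. It gave 171 (without EILP_WT replicate 3) to 380 in EILP_WT vs ALP_WT, with 240 and 222 without ALP_WT replicates 1 and 2, and 643 to 788 in ILCP_WT vs EILP_WT. It gave 0 to 7 (without sEILP_WT replicate 2) in cEILP_WT vs sEILP_WT, with 1 without cEILP_WT replicate 2. It gave 20 (without sEILP_WT replicate 2) to 110 in sEILP_WT vs ALP_WT, with 27 and 26 without ALP_WT replicate 1 and sEILP_WT replicate 1. It gave 509 (without cEILP_WT replicate 3) to 754 in ILCP_WT vs cEILP_WT, with 590 and 548 without cEILP_WT replicates 1 and 2, and 93 (without ALP_WT replicate 1) to 157 in EILP_KO vs ALP_WT, with 102 without EILP_KO replicate 2. Of the 51 gene list tests called by camera, 0 were called with an estimated correlation, 48 with the replicate block, 49 without the batch term and 51 without sort gate genes, the last chosen after the data were seen. In EILP_KO vs EILP_WT, the median of genes higher in sEILP_WT than in ALP_WT stayed between -0.61 and -0.39 when 1 library was left out. 2 uncalled stage sets turned camera's direction there: genes lower in ILCP_WT than in cEILP_WT had a median of -0.05 without EILP_WT replicate 3 (adjusted p = 0.993), the lowest of a range up to 0.29, and genes lower in sEILP_WT than in ALP_WT were placed higher, with a median of 0.07, without EILP_KO replicate 1 (adjusted p = 0.971), within a range of -0.09 to 0.13. The median of genes higher in ILCP_WT than in cEILP_WT, also uncalled, turned from -0.10 to 0.02 without EILP_WT replicate 1, without EILP_WT replicate 3 and without the batch term, while camera's direction stayed. The depth of the libraries is unknown, so what it limits could not be measured.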

Other observations

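The tests of ALP-like cells, of the sex-linked reads in the ILCP_WT comparisons and of other splits of the samples were chosen after the result was seen, as was the cyclic loess scaling. The other tests were set down before their results were seen, on patterns found in the same data.

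The set of genes that rose from ALP_WT to sEILP_WT was shifted down in EILP_KO against EILP_WT, with a median of -0.49 over 62 genes, of which Tcf7 itself passed the threshold and the others did not. Members above the lowest value in all 5 libraries kept a median of -0.48 (SE 0.15), against loss to that value as the whole cause. A fit with terms for Y and Xist reads kept a median of -0.69 (SE 0.22), against sex as the whole cause. The SEs of medians here take genes as independent. The estimated correlation within the set was 0.107, so these SEs are too small and measure no spread between libraries. Both arguments rest on the medians keeping their size. ALP-like cells among the sorted mutant cells would need a share of 34% to lower the set by its median. The EILP gate takes a4b7+ cells and ALP_WT was sorted as a4b7-. The a4b7 gene Itgb7 differed by -0.11 (SE 0.28) in EILP_KO vs EILP_WT. The other a4b7 gene, Itga4, rose over ALP_WT by less in EILP_KO than in EILP_WT, so these genes do not decide. The needed share was tested on the 30 genes that fell in EILP_WT, had at least 5 log2 units in every ALP_WT library and would rise by at least 1 log2 unit over EILP_WT. In EILP_KO their median was -1.3 (SE 0.72) relative to the level the share would bring, and 28 lay below it. The medians in EILP_KO replicates 1 and 2 were -1.27 and -1.41. These values of the 30 genes as a set argue against ALP-like cells as the whole cause, within the limit of the SE given above. Chosen after their values were seen, Cmah, Tlr7, Emp1 and Ddx4 were over 10-fold below it in both EILP_KO libraries. All of them were at the lowest value there, the rest of the 30 were not 10-fold below in both, and the argument does not rest on them. Cells of a type not sorted here stay open, since the series holds no profile of them and 15 of 18 myeloid genes were positive. A different mix of sEILP and cEILP cells among the mutant cells was not tested and stays open too. The genes toward cEILP_WT had a median of -0.55 in EILP_KO vs EILP_WT, those toward sEILP_WT of 0.21. A rise that partly needs Tcf7 is a candidate explanation beside these, as a hypothesis found in these data that the tests here do not decide.

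More genes were lower than higher in ILCP_WT against both EILP_WT and cEILP_WT. Loss to the lowest value was argued against: of changed genes above it in every library of both groups, at least 64.8% were lower, and 60.6% to 79.2% when 1 library was left out. Centring the libraries left 58.6% lower but moved each library by only -0.05 to 0.02, so it decided nothing about the normalization, and cyclic loess brought the split to 447 lower of 838 and 460 of 846. For ILCP_WT vs EILP_WT, leaving out EILP_WT replicate 1, the EILP_WT library with Y reads, left 59.7% lower, against sex as the whole cause. With terms for Y and Xist reads, 110 of 145 changed genes in ILCP_WT vs cEILP_WT were lower, or 75.86%. The SE of that share, 3.554, takes genes as independent. Every cEILP_WT library and no ILCP_WT library had Y reads. These terms therefore rest on the other groups and cannot decide about sex in this comparison, where it stays open. The normalization stays open as well, and no biological reading is offered.

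Genes that rose from ALP_WT to EILP_WT lay beside each other more often than genes of random sets did. Of 193 risers with a position, 30 had another riser within 100 kb without overlapping it, against a median of 12 and a 95% point of 20 over 10000 random sets matched on expression (permutation p = 0.0004), and Fgf3 and Fgf15 lay 52.1 kb apart. Shared reads were argued against, as 0 of the 17 pairs shared a 25-base sequence, and so was gene density, as sets also matched on it had a 95% point of 18 (permutation p = 0.0002). Transcripts that run on into the next gene stay open, since divergent pairs held 4 risers against a 95% point of 7. A630014C17Rik overlaps Tcf7 and was counted through Skp1a, and overlapping genes were not checked for shared sequence. The permutation takes the risers as given and measures no spread between libraries, and the count was not repeated with a library left out. Shared regulation of neighbouring genes may contribute, as a hypothesis found in these data.

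Aff4 lies 1.07 Mb from Tcf7 and was lower in EILP_KO, so a region around the changed allele in which several genes differ was tested. Of 81 tested genes within 5 Mb of Tcf7, 9 had an unadjusted p under 0.05, against a median of 7 and a 95% point of 12 over 10160 windows elsewhere. Tcf7 alone was left out, so Aff4, which prompted the test, is among the 9 (limma unadjusted p = 1.02e-05). The bound set beforehand, at or below the 95% point, was wrong: 9 lay above the median and 28.9% of the windows had as many, so the count decides neither way. A630014C17Rik, which overlaps Tcf7 and was chosen after its values were seen, was among the 9 and lower by 5.6 (SE 1.71, unadjusted p = 0.00659). With Aff4 and A630014C17Rik counted, a place above the median is no sign of a wider region. Such a region stays open.

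The 6 libraries of EILP_WT and ALP_WT can be split in 10 ways into groups of 3, too few for a share under 0.05. The real split was the 1 with 404 changed genes, and the highest of the others gave 0.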
